A study of Mus musculus with 9 samples.

How the data were processed

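RNA sequencing was done on 9 mouse samples purified by cell sorting. The epidermal samples were keratinocytes of adult skin, with 2 libraries of the WT group and 2 of the Mi2 group. The regulatory T cell (Treg) samples came from skin-draining lymph nodes, with 2 control libraries (Ctl), 2 libraries of TSLPR WT Tregs from Mi2 mice and 1 library of TSLPR-negative Tregs from Mi2 mice. TSLPR is the receptor chain for the cytokine TSLP and is encoded by Crlf2. Mi-2β is the chromatin remodelling ATPase encoded by Chd4. The column names mark the Mi2 libraries as knock-outs, and they call the Tregs skin Tregs where the sample labels give skin-draining lymph nodes. The labels do not say whether the replicates of a group came from different mice, how TSLPR-negative cells were obtained, or which of the listed library kits (NEXTflex or stranded TruSeq) served each sample.

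The labels list bcl2fastq 1.8.3, STAR, DESeq2 and the mouse builds mm9 and mm10, with no role given for each build. The deposited signal of both tables was a normalized read count that the authors made by multiplying whole reads by 1 factor per library. Every value above 0 in each of the 9 columns was a whole multiple of the step for 1 read, within 0.05 reads, so reads were recovered by dividing by that step. The epidermal table held 36442 Ensembl genes and was scaled by size factors, as its DESeq2 file label and unequal column totals show. The counting program and the strand setting of the epidermal table are not given in the sources used here. Per its headers, the authors made the Treg table with HOMER, counting reads in exons of RefSeq transcripts on mm9 and naming DESeq2 for scaling. The command listed 7 libraries, of which the table holds 5, and no strand setting. All 5 columns had 1 common total, which size factors would not give. Transcripts of 1 gene share reads in that table, so each of the 24016 symbols was represented by the transcript with the highest mean, out of 33022 transcripts. Current symbols were found for 31819 of the epidermal IDs and 32612 of the Treg transcripts, and list members were matched by either the table's symbol or the current one.

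The epidermal libraries held between 5682391 and 8913804 recovered reads over genes. The Treg libraries held between 21849381 and 32238992 over all transcripts. A fold against a group with 0 reads was computed against 3 reads in each library of that group and written as at least that fold. With 1 to 3 reads, the ratio is given with its 95% exact counting interval. Reads carried no molecular identifiers, so these intervals and floors cover counting error alone.

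Before the data were examined, the groups, comparisons, gene lists, the rule for named genes and most alternative settings were fixed. That design put raw counts first and named a test for normalized values otherwise; since the tables held normalized values, the second test was used. limma 3.58.1 with an intensity trend was run in R 4.3.3 on log2(value + 1), after genes with a mean under 10 over the fitted libraries were left out. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The epidermal fit used 4 libraries, and the 3 Treg comparisons came from 1 fit of 5 libraries, in which the lone TSLPR-negative library was assumed to vary like the other groups. All tests were two-sided. The fit was tested on simulated data with 200 changed genes per comparison and 1 assumed dispersion, 0.05 in epidermis and 0.04 in Tregs. In epidermis it recovered 24% of 2-fold and 97% of 4-fold changes among 14344 genes, with 9 false calls among 130. For TSLPR WT Mi2 against Ctl Tregs it was 47% and 100% among 12287 genes, with 4 false calls among 151. For TSLPR-negative against TSLPR WT it was 26% and 96% among 12292, with 2 among 124. These rates describe such simulated data, not the real comparisons. With 2 libraries per group at most, no regrouping of samples and no test for outlying samples applied.

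Named genes were the 10 largest rises and 10 largest falls by fitted log2 change among called genes with a mean of at least 20 and groups that did not overlap, up to 4 members with the smallest p of each gene list, the 3 most abundant genes of each marker list, Chd4, Chd3, Tslp and Il33 in epidermis, and Foxp3, Crlf2, Il7r, Gata3 and Il1rl1 in Tregs. Some genes that this rule names are not reported here. Gene lists covered epidermal programmes, Treg programmes, general cell programmes and markers of other cell types that a sort could hold. Each list of at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 comparison. camera was also run with a correlation estimated from the data, and fry asked whether the genes of a list move on balance one way. Members are counted among all genes tested and also adjusted over the list alone. Correlation and covariance of changes in the Treg comparisons were set beside 100 simulations of unchanged groups that share the control libraries.

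The alternatives were another pseudocount (0.5 or 5), no filter or a mean of at least 50, TMM on top, quantile, size factor and upper quartile scaling, scaling without the 50 most abundant genes, no intensity trend, edgeR 4.0.16, DESeq2 1.42.0 and voom on recovered reads, an adjusted p under 0.01, a change of at least 1.5-fold, leaving out each replicate, a replicate block and the Treg groups fitted without the lone library. Chosen after seeing the data were the longest transcript or every transcript per symbol, mitochondrially encoded genes left out before rescaling, edgeR with no filter, 1 Ctl library for each of the 2 Treg comparisons against Ctl, and list counts without the libraries in doubt. The libraries in doubt were Mi2 epidermis replicate 1, for its share of mitochondrial reads, and Ctl Treg replicate 2, for its mixture of Xist and Y-linked reads. Figures were drawn with matplotlib. Whether the part of Chd4 or Crlf2 that a deletion would remove lies in the counted exons is not given in the sources used here.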

Results

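The data describe sorted epidermal keratinocytes and sorted Tregs of mice with and without the Mi2 alteration. Each epidermal group and the Ctl and TSLPR WT Mi2 Treg groups had 2 libraries, and the TSLPR-negative group had 1. Depth was 7002100 and 8913804 reads in WT and 7662946 and 5682391 in Mi2 epidermis. It was 21849381 and 32238992 in Ctl, 29314512 and 25973974 in TSLPR WT Mi2 and 30629057 in TSLPR-negative Mi2 Tregs. Mitochondrially encoded genes took 13.8% and 12.9% of reads in WT and 29.7% and 15.5% in Mi2 epidermis, with the highest share in Mi2 replicate 1. Across genes, which are not independent replicates, log2 values of the WT libraries correlated at 0.978 and those of the Mi2 libraries at 0.938.

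The first comparison asks which keratinocyte genes differ in Mi2 epidermis. Tslp, the cytokine that TSLPR binds, rose from 15.9 and 16.0 normalized reads in WT to 2780 and 3132 in Mi2 epidermis (log2 change 7.45, SE 0.208, adjusted p = 2.6e-05). Il33, an alarmin cytokine, fell from 789 and 712 to 47.8 and 58.6 (log2 change -3.80, SE 0.224, adjusted p = 4.2e-04). Most tested genes of the stress keratin, cell cycle, glycolysis and cholesterol synthesis lists were called higher (camera adjusted p = 0.504 for each with an estimated correlation). With so few libraries, the check with an estimated correlation had little power. Chd4 itself fell from 1607 and 1942 to 734 and 1207 (mean 1774 ± 237 against 970 ± 335, SD; log2 change -0.91, SE 0.272, adjusted p = 0.0456), and Chd3, its paralog, fell by 0.81 on the log2 scale (SE 0.192, adjusted p = 0.0222). In all, 4085 of 14461 genes were called, 2185 higher and 1900 lower in Mi2. The balance of directions depends on the scaling. It was 1751 and 2102 without the 50 most abundant genes. It was 1531 and 2749 with mitochondrial genes left out, a choice made after seeing the data. The call of Chd4 ended without WT replicate 1, WT replicate 2 or Mi2 replicate 1, with log2 changes of -1.04, -0.77 and -0.55. That of Chd3 ended without either WT library, with -0.81 each time. The call of Chd4 also ended with edgeR (adjusted p = 0.0538), with no filter (0.0754) and with limma without trend (0.108), as did that of Chd3 without trend (0.0677). With 1 library left out, only the other group's pair sets the spread, and the WT pair correlated more closely (0.978) than the Mi2 pair (0.938). An ended call or moved count then need not mean that a change rests on the left-out library.

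Among subunits of the NuRD complex, to which Chd4 and Chd3 belong, 4 of 15 rose, 2 fell and 9 were not called, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.141, 0.504 with an estimated correlation). Chd5, a further paralog, rose from 0 and 0.726 to 241 and 215 normalized reads, with 1 read in WT, a ratio of 629 (95% interval 94.9 to 21077). Gatad2a rose by 1.17 and Cdk2ap1 by 1.16 on the log2 scale. The subunits called higher and lower were 1 and 0 without WT replicate 1, 2 and 0 without WT replicate 2 and 4 and 1 without Mi2 replicate 1. The call of Gatad2a ended without WT replicate 1, and that of Cdk2ap1 without either WT library and without trend (adjusted p = 0.0556).

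**Figure D1:**
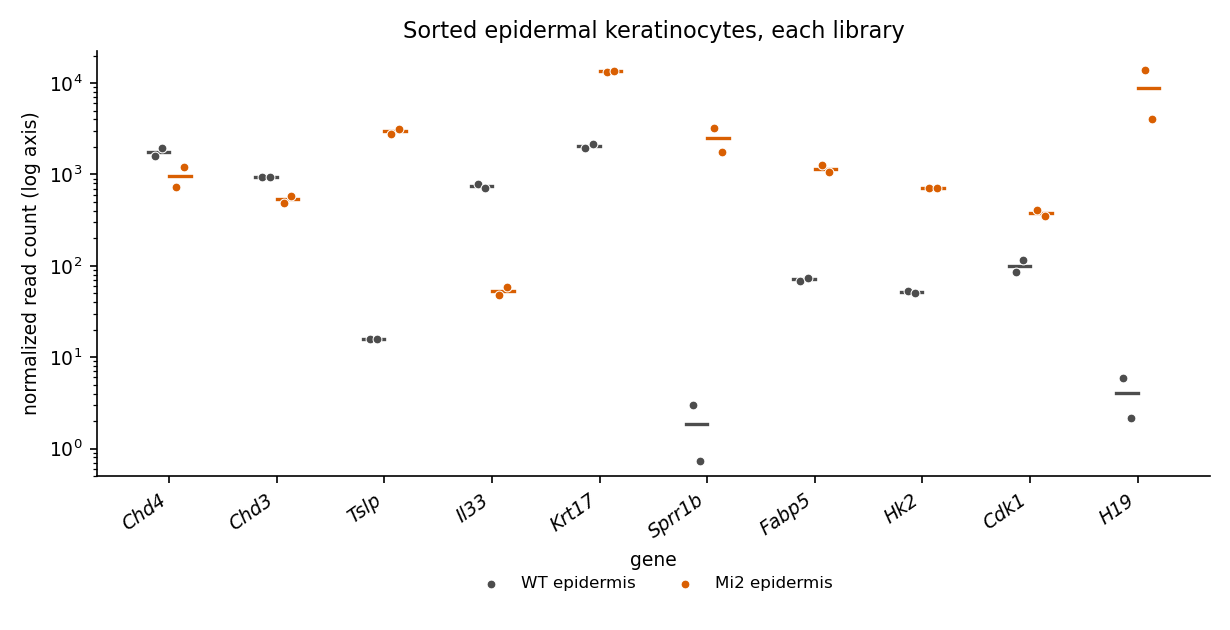
Normalized read counts on a log axis of 10 genes in each library of WT (grey) and Mi2 (orange) epidermis, with bars at the mean of the 2 libraries. Tslp stands at 15.9 and 16.0 in WT and at 2780 and 3132 in Mi2 epidermis, and Il33 at 789 and 712 against 47.8 and 58.6.

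By fitted change of log2(value + 1), the largest rises were in H19, an imprinted noncoding RNA on chromosome 7, from 5.95 and 2.18 to 13784 and 4004 normalized reads (log2 change 10.63, SE 0.598), and in Sprr1b, a cornified envelope precursor, from 2.98 and 0.726 to 3252 and 1752 (log2 change 9.83, SE 0.477). Stfa1 and Gpr128 rose by 9.26 and 8.37 on the log2 scale. Padi3, a protein-citrullinating enzyme of the epidermis, was at least 221-fold higher, Sprr2h at least 174-fold, Tcfl5 at least 120-fold and Mir675, which lies within H19 and shares its reads, at least 113-fold, each with 0 reads in WT. Pi15 had 1 read in WT, a ratio of 3255 (95% interval 496 to 109282), and Klk13 also had 1 read, a ratio of 830 (126 to 27938). Members of the Sprr2 and Stfa families are similar in sequence, so their reads may be split or shared by the counting.

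The largest fitted falls were in genes that WT keratinocytes expressed at low to moderate levels. Arsi was at least 37.9-fold lower, Rspo3, a Wnt pathway agonist, at least 27.9-fold, Ccdc27 at least 15.5-fold and RNaseP_nuc.5 at least 11.9-fold, each with 0 reads in Mi2 epidermis. Npr3, a natriuretic peptide receptor, had 1 read in Mi2, a ratio of 0.00270 (95% interval 6.4e-05 to 0.0142), and Gabrp had 3 reads, a ratio of 0.00837 (0.00165 to 0.0235). Mesp2 had 2 reads, a ratio of 0.00640 (7.7e-04 to 0.0230), Zfr2 had 1, a ratio of 0.00594 (1.4e-04 to 0.0319), and Tgm7 had 3, a ratio of 0.0164 (0.00316 to 0.0454). Ccbp2, a chemokine scavenging receptor, fell by 5.73 on the log2 scale. The calls of Ccdc27 and RNaseP_nuc.5 ended without WT replicate 1.

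Stress keratins and antimicrobial genes rose, with 8 of 10 members higher, 0 lower and 2 not called, also 8 adjusted over the list alone and 8 without Mi2 replicate 1 (camera adjusted p = 3.0e-05, 0.504 with an estimated correlation). With Mi2 replicate 2 left out, 1 was lower. Krt17, a keratin of wounded and hyperproliferative epidermis, rose from 1957 and 2143 to 13321 and 13623 normalized reads, and Sprr2a3 rose by 5.78 on the log2 scale. Lcn2 had 2 reads in WT, a ratio of 198 (95% interval 45.6 to 1385). Cornified envelope and suprabasal genes went both ways, with 13 of 30 higher, 7 lower and 10 not called, 13 and 8 adjusted over the list alone (camera adjusted p = 0.0318 upward, 0.572 with an estimated correlation). Dsc1, a desmosomal cadherin of differentiating cells, and Sprr1a rose by 3.83 and 4.40 on the log2 scale, and Tgm1, the transglutaminase that links the envelope, had 3 reads in WT, a ratio of 202 (79.8 to 1143). Without Mi2 replicate 1 the list had 12 higher and 7 lower, without Mi2 replicate 2 its camera adjusted p was 0.175, and without WT replicates 1 and 2 in turn 2 and 3 members were lower. Desmosome and tight junction genes had 6 of 23 higher, 2 lower and 15 not called, 9 and 2 adjusted over the list alone, also 6 and 2 without Mi2 replicate 1 and 10 higher without Mi2 replicate 2 (camera adjusted p = 0.0382 upward, 0.504 with an estimated correlation). Dsc2 and Gjb2 rose by 5.19 and 4.36 on the log2 scale.

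Lipid barrier genes rose, with 11 of 23 higher, 1 lower and 11 not called, 13 and 2 adjusted over the list alone (camera adjusted p = 1.1e-04, 0.504 with an estimated correlation). Degs1, a ceramide desaturase, rose by 2.22 on the log2 scale, Abca12, a keratinocyte lipid transporter, by 1.71, and the ceramide synthase that the table calls Lass3 by 1.73. Cholesterol synthesis genes rose in 12 of 20 cases, with 0 lower and 8 not called, also 12 adjusted over the list alone (camera adjusted p = 4.0e-05, 0.504 with an estimated correlation). Sqle, which is on both lists, rose by 2.10 on the log2 scale. Without Mi2 replicate 1, 11 lipid barrier and 11 cholesterol genes were higher. Without WT replicate 1 the 2 counts were 7 and 5, and without WT replicate 2 the cholesterol count was 6. No lipid barrier gene was lower without either WT library.

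Cell cycle genes rose, with 22 of 34 higher, 0 lower and 12 not called, 24 adjusted over the list alone and 20 without Mi2 replicate 1 (camera adjusted p = 1.5e-09, 0.504 with an estimated correlation). Cdc20, Rrm2 and Plk1, which act in mitosis and nucleotide synthesis, rose by 2.39, 2.77 and 3.62 on the log2 scale. Glycolysis and hypoxia genes had 15 of 23 higher, 1 lower and 7 not called, 16 and 2 adjusted over the list alone and 13 and 1 without Mi2 replicate 1 (camera adjusted p = 1.7e-05, 0.504 with an estimated correlation). Hk2, a hexokinase, rose from 53.6 and 50.8 to 703 and 718 normalized reads, the lactate transporter gene Slc16a3 by 3.73 on the log2 scale and Ldha by 2.09. Unfolded protein response genes had 11 of 22 higher, 1 lower and 10 not called, 12 and 1 adjusted over the list alone and 9 and 0 without Mi2 replicate 1 (camera adjusted p = 0.00661, 0.504 with an estimated correlation). The chaperones Hyou1 and Calr rose by 1.34 and 1.35 on the log2 scale. Without WT replicate 1 and WT replicate 2 in turn, 1 and 5 of these genes were higher. Of glycolysis and unfolded protein response genes, 0 and 0 were lower without either WT library, and 3 and 3 without Mi2 replicate 2. The shares of mitochondrial reads, 13.8% and 12.9% in WT and 29.7% and 15.5% in Mi2 epidermis, stand beside all of these groups.

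Class I antigen presentation genes had 5 of 19 higher, 0 lower and 14 not called, also 5 adjusted over the list alone (camera adjusted p = 0.0239, 0.718 with an estimated correlation). Psmb10, an immunoproteasome subunit, rose by 1.20 and Tap2, a peptide transporter, by 0.80 on the log2 scale, and the call of Tap2 ended with no filter, without the 50 most abundant genes in scaling and without trend (adjusted p = 0.0597, 0.0825 and 0.0934). Without Mi2 replicate 1, 8 members were higher; without WT replicate 1 and WT replicate 2 in turn 0 were higher, and the camera adjusted p was 0.0752 without WT replicate 1 and 0.248 without Mi2 replicate 2, where 3 were higher and 1 lower. Cytokines and growth factors had 7 of 16 higher, 4 lower and 5 not called, 8 and 4 adjusted over the list alone and 7 and 4 without Mi2 replicate 1 (camera adjusted p = 0.132, 0.504 with an estimated correlation). The counts were 5 and 2 without WT replicate 1 and 7 and 2 without WT replicate 2. Over 2 scalings and 4 left-out libraries that list's camera adjusted p ran from 0.0311 to 0.244, under 0.05 upward without either WT library. Beside Tslp and Il33, Il34, a ligand of the macrophage growth factor receptor, fell by 2.81 and Tgfa, a ligand of the epidermal growth factor receptor, rose by 2.95 on the log2 scale. Of 9 chemokines, 3 rose, 2 fell and 4 were not called, also 3 and 2 adjusted over the list alone and 4 and 2 without Mi2 replicate 1 (camera adjusted p = 0.828, 0.926 with an estimated correlation). For chemokines they were 1 and 2 without WT replicate 1 and 1 and 1 without WT replicate 2. Cx3cl1 fell by 3.13 on the log2 scale, Ccl27a, a skin-homing chemokine, fell by 2.38, Cxcl9 rose by 4.29, and Ccl22 was at least 7.76-fold higher, with 0 reads in WT. The Ccl22 call ended without either WT library. That of Ccl27a ended without WT replicate 2 and without trend (adjusted p = 0.0538), and that of Cxcl9 with voom (0.0539).

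The other epidermal lists did not pass camera, though 4 did with a library left out. Basal and hemidesmosome genes had 4 higher and 3 lower of 21 (camera adjusted p = 0.360), with Cd44 higher by 2.25 on the log2 scale and Krt15, a keratin of basal and hair follicle stem cells, lower, from 49093 and 40508 to 4202 and 8781 normalized reads. Hair follicle genes had 8 higher and 3 lower of 21 (0.132), with Gli1, a Hedgehog target, and Cd34 higher by 3.62 and 4.22. Notch pathway genes had 4 higher and 1 lower of 15 (0.362), and retinoid and vitamin D genes 2 higher and 3 lower of 12 (0.783), with Crabp2 higher by 3.71. The p53 target genes had 9 higher and 2 lower of 24 (0.0653), type I interferon response genes 6 and 1 of 17 (0.342), immediate early and dissociation genes 4 and 2 of 22 (0.783), NF-kB response genes 4 and 1 of 17 (0.430) and oxidative phosphorylation genes 5 and 1 of 29 (0.132). Adjusted over the list alone the higher and lower members were 4 and 3, 9 and 3, 5 and 1, 2 and 3, 9 and 2, 7 and 1, 4 and 2, 4 and 1, and 5 and 1, in that order. Without either WT library, none of these lists had more members called than with all libraries, and there the Mi2 pair alone sets the spread. With Mi2 replicate 2 left out, interferon genes had 3 and 5, immediate early genes 5 and 6, NF-kB response genes 3 and 5, p53 target genes 9 and 4, basal genes 7 and 4, Notch genes 4 and 2 and oxidative phosphorylation genes 8 and 1. Without Mi2 replicate 1, oxidative phosphorylation genes had 1 and 0, and interferon and Notch genes 5 and 2 each. With an estimated correlation the adjusted p of these lists lay at 0.504 or above. Over the same 6 settings the camera adjusted p ran from 0.0422 to 0.865 for NF-kB response, 0.0355 to 0.688 for oxidative phosphorylation, 0.0259 to 0.411 for hair follicle and 0.0197 to 0.209 for p53 target genes. It was under 0.05 upward without WT replicate 2 or Mi2 replicate 1 for the first, without WT replicate 1 or Mi2 replicate 2 for the second and without Mi2 replicate 1 for the last 2.

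**Figure D2:**
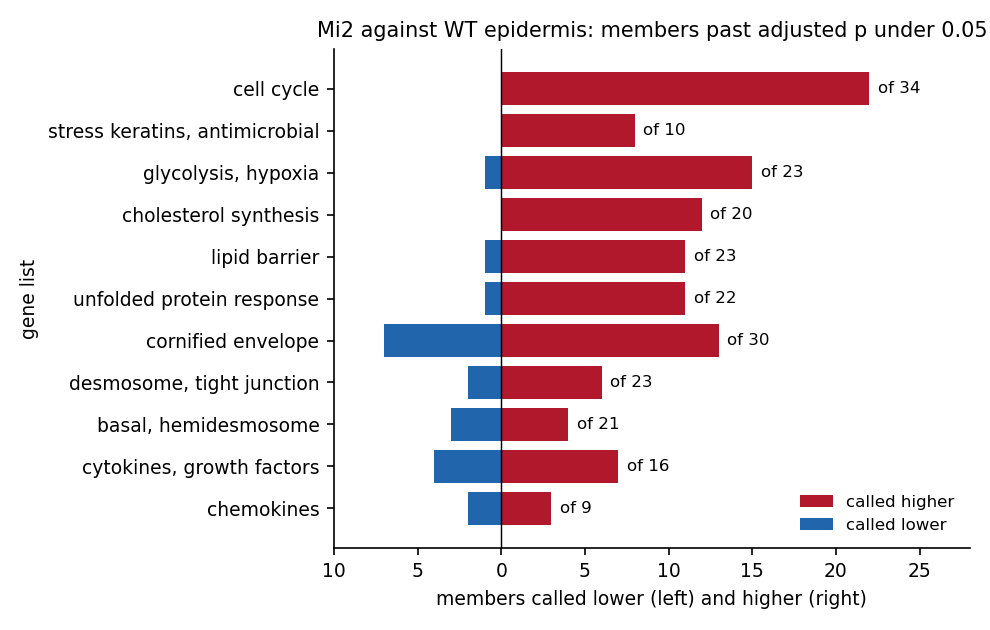
Number of members called higher (red, right) and lower (blue, left) in Mi2 against WT epidermis for 11 gene lists, with the number of tested members beside each bar. Cell cycle genes had 22 of 34 higher and 0 lower, and cornified envelope genes 13 higher and 7 lower of 30.

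Erythroid genes, as markers of other cells, had 4 of 5 lower and 0 higher, also 4 adjusted over the list alone (camera adjusted p = 0.0239, 0.654 with an estimated correlation), with Hba-a1 at 283 and 849 normalized reads in WT and 57.1 and 109 in Mi2. Globin paralogs share reads. Without Mi2 replicate 1, 0 were called (camera adjusted p = 0.0795), and without Mi2 replicate 2 it was 0.140. Without WT replicate 2, 2 were lower. Sebocyte genes had 2 of 5 higher, 0 lower and 3 not called, also 2 adjusted over the list alone and 3 without Mi2 replicate 1 (camera adjusted p = 0.0239, 0.0716 without Mi2 replicate 2, 0.504 with an estimated correlation). Without either WT library 1 was higher. Fabp5, which proliferating keratinocytes also express, stood at 68.5 and 73.3 against 1255 and 1058. Langerhans and dendritic cell genes had 3 higher and 0 lower of 8 (camera adjusted p = 0.0544, 0.0119 to 0.234 over the 6 settings, under 0.05 upward without WT replicate 1 and without Mi2 replicate 1), of which Mfge8 stood at 20.8 and 21.1 in WT and 756 and 560 in Mi2 while Cst3 stood at 1604 and 1282 against 853 and 970. T lymphocyte genes had 1 higher and 1 lower of 3 (0.904), melanocyte genes 0 and 1 of 3 (0.601), fibroblast and dermis genes 1 and 1 of 5 (0.601), neutrophil and macrophage genes 0 and 0 of 3 (0.841) and neuron genes 2 and 1 of 3 (0.430). The lower ones of T lymphocyte, fibroblast and neuron genes numbered 0 without either WT library. Then 1 neuron gene was higher. With Mi2 replicate 2 left out, Langerhans genes had 3 and 1, T lymphocyte genes 1 and 0 and melanocyte genes 1 and 2, and with Mi2 replicate 1 left out, fibroblast genes had 1 and 2 and neuron genes 1 and 0. Neutrophil and macrophage genes had 0 and 1 without WT replicate 1 and 1 and 0 without WT replicate 2. Thy1 stood at 265 and 151 in WT and 1631 and 812 in Mi2, Sparc at 595 and 400 against 2944 and 1711, and Lyz2, a myeloid gene, at 0.992 and 182 against 1.33 and 2.72. Endothelial, mast cell and muscle lists had 1, 0 and 1 tested members, too few for a test. Mitf, a melanocyte regulator, stood at 76.4 and 96.6 in WT and 7.96 and 6.81 in Mi2 epidermis.

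The next comparison asks how Tregs with intact TSLPR in Mi2 mice differ from Ctl Tregs. Lgals3, a galectin of effector cells, rose from 363 and 188 normalized reads in Ctl to 3851 and 3304 in TSLPR WT Mi2 Tregs (mean 275 ± 124 against 3577 ± 387, SD; log2 change 3.77, SE 0.277, adjusted p = 3.6e-06). Cdk1, a mitotic kinase, rose from 462 and 275 to 2562 and 2952 (log2 change 2.94, SE 0.253, adjusted p = 7.4e-06). Of 21 resting Treg and 28 type I interferon response genes, 16 and 25 were called lower (camera adjusted p = 0.538 for both with an estimated correlation). Among the resting genes, the survival gene Bcl2 fell from 10038 and 6422 to 995 and 1923 (log2 change -2.54, SE 0.289, adjusted p = 2.6e-05). Foxp3, the transcription factor that defines Tregs, stood at 11159 and 15371 in Ctl and 13778 and 14517 in TSLPR WT Mi2 (log2 change 0.11, SE 0.225, adjusted p = 0.755). In all, 3383 of 12206 genes were called, 1791 higher and 1592 lower in TSLPR WT Mi2. Without Ctl replicate 2, the library in doubt, the count was 2635. Xist stood at 25266 and 8678 in Ctl and 19.4 and 6.97 in TSLPR WT Mi2 Tregs, and the sum of 4 Y-linked genes at 8.28 and 2289 against 5707 and 4382, so sex-linked reads separate these groups, with Ctl replicate 2 holding both kinds.

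Gata3 stood at 1880 and 2046 in Ctl and 2282 and 1900 in TSLPR WT Mi2 Tregs (log2 change 0.09, adjusted p = 0.793), and Crlf2 at 395 and 742 against 816 and 715 (log2 change 0.50, SE 0.300, adjusted p = 0.240). Il7r, the partner chain of TSLPR, stood at 13149 and 4762 against 16939 and 5188 (log2 change 0.24, SE 0.464). Il1rl1, the receptor for the cytokine of Il33, rose from 1330 and 751 to 3420 and 1636 (log2 change 1.24, SE 0.320, adjusted p = 0.00987), and its call ended without Ctl replicate 2 (log2 change 0.83, adjusted p = 0.0746) and without TSLPR WT Mi2 replicate 1 (0.71, 0.0822), and also without trend (adjusted p = 0.0959).

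Besides the Y-linked genes Eif2s3y, Uty, Ddx3y and Kdm5d, the largest fitted rises were in Ranbp17, Dact2, Slc17a8, Maats1, Oit3 and Amotl1. Ranbp17 had 1 read in Ctl, a ratio of 137 (95% interval 29.0 to 6499), and Dact2 had 2, a ratio of 50.7 (11.2 to 349). Slc17a8, Maats1, Oit3 and Amotl1 rose by 4.60, 4.51, 4.50 and 4.49 on the log2 scale. The calls of Uty and Kdm5d ended without Ctl replicate 1 (adjusted p = 0.139 and 0.433), and those of all 4 Y-linked genes with DESeq2 (0.413 to 0.730). Besides Xist and its antisense partner Tsix, which overlap with no strand setting given, the largest fitted falls were in Oas2, Ntn4, Ifit1, Igj, Oasl2, Ifit3, Slc16a5 and Rec8. Log2 changes of these 8 genes ran from -4.02 for Oas2 to -3.51 for Rec8, and the call of Ntn4 ended with DESeq2 (adjusted p = 0.167).

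**Figure D3:**
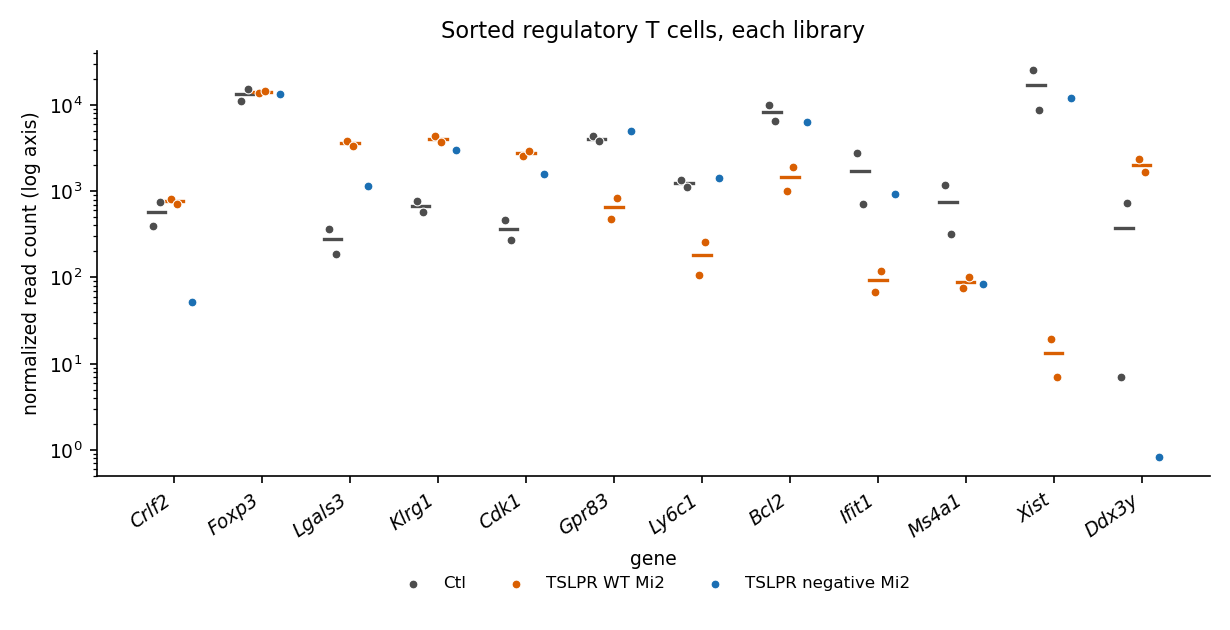
Normalized read counts on a log axis of 12 genes in each library of Ctl (grey), TSLPR WT Mi2 (orange) and TSLPR-negative Mi2 (blue) Tregs, with bars at the mean of 2 libraries. Crlf2 stands at 51.5 in the TSLPR-negative library against 816 and 715 in TSLPR WT Mi2, and Lgals3 at 1148 there against 363 and 188 in Ctl.

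Cell cycle genes rose in all 34 of 34 cases over this test, also 34 adjusted over the list alone and 34 without Ctl replicate 2 (camera adjusted p = 1.9e-30, 0.538 with an estimated correlation). Aurkb, Plk1 and Rrm2 rose by 2.88, 2.89 and 2.66 on the log2 scale. Effector Treg genes had 26 of 38 higher, 1 lower and 11 not called, also 26 and 1 adjusted over the list alone and 25 and 0 without Ctl replicate 2 (camera adjusted p = 4.8e-12, 0.538 with an estimated correlation). Klrg1, a receptor of terminally differentiated Tregs, rose from 767 and 574 to 4314 and 3738 normalized reads, and the calcium-binding S100a6 and S100a4 by 2.24 and 2.10 on the log2 scale. Glycolysis and hypoxia genes had 10 of 22 higher, 1 lower and 11 not called, also 10 and 1 adjusted over the list alone and 10 and 1 without Ctl replicate 2 (camera adjusted p = 0.00228, 0.538 with an estimated correlation). Tpi1 and Pkm rose by 1.95 and 1.48 on the log2 scale. Oxidative phosphorylation genes had 10 of 29 higher, 0 lower and 19 not called, 13 adjusted over the list alone and 8 without Ctl replicate 2 (camera adjusted p = 3.5e-04, 0.749 with an estimated correlation), with Cox5a and Sdhb higher by 0.83 and 0.80. Without Ctl replicate 1 that count was 1, and without TSLPR WT Mi2 replicate 2 it was 0 (camera adjusted p = 0.0811). Sex-linked reads moved with each of these groups, with Xist at 25266 and 8678 in Ctl and 19.4 and 6.97 in TSLPR WT Mi2.

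Resting and central Treg genes fell, with 16 of 21 lower, 1 higher and 4 not called, the same adjusted over the list alone, and 15 and 0 without Ctl replicate 2 (camera adjusted p = 7.4e-08, 0.538 with an estimated correlation). The higher count was 0 without TSLPR WT Mi2 replicate 1 and 2 without TSLPR WT Mi2 replicate 2. Ly6c1 fell from 1347 and 1120 to 108 and 256 normalized reads, and Evl and Actn1 fell by 2.65 and 2.21 on the log2 scale. Type I interferon response genes had 25 of 28 lower, 0 higher and 3 not called, 27 adjusted over the list alone and 25 without Ctl replicate 2 (camera adjusted p = 3.3e-16, 0.538 with an estimated correlation). Usp18 and Irf7 had log2 changes of -3.31 and -2.03. The list's median was -1.82, and -2.32 without Ctl replicate 2, so the size of the fall rests in part on Ctl replicate 1. Ifit1 stood at 2748 and 702 in Ctl against 67.9 and 117. Genes that respond to T cell receptor signals had 12 of 22 lower, 5 higher and 5 not called, 13 and 5 adjusted over the list alone and 8 and 5 without Ctl replicate 2 (camera adjusted p = 0.00823 downward, 0.538 with an estimated correlation). Egr2, Egr3 and Nr4a3, which are induced by that signal, had log2 changes of -2.04, -1.91 and -1.94. Without Ctl replicate 1 that list had 7 lower and 2 higher, and without TSLPR WT Mi2 replicate 1 it had 2 higher. Ctl replicate 2, at 45.4% of the mean Y-linked sum of TSLPR WT Mi2 Tregs, stands beside these groups too.

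TSLP and STAT5 signalling genes had 9 of 24 lower, 0 higher and 15 not called, also 9 adjusted over the list alone and 6 lower and 1 higher without Ctl replicate 2 (camera adjusted p = 0.00228, 0.538 with an estimated correlation). It had 5 lower and 1 higher without TSLPR WT Mi2 replicate 2. Besides Bcl2, Lta and Socs1, a feedback inhibitor of cytokine signals, were among the members with the smallest p, with log2 changes of -2.13 and -1.62. Class I antigen presentation genes had 8 of 19 lower, 0 higher and 11 not called, also 8 adjusted over the list alone (camera adjusted p = 0.00228, 0.749 with an estimated correlation). Nlrc5, their transcriptional activator, fell from 9788 and 11026 to 2826 and 4284 normalized reads. Without Ctl replicate 2, 3 members were lower, and without TSLPR WT Mi2 replicate 1 also 3 (camera adjusted p = 0.147). Type 2 genes had 6 of 12 higher, 2 lower and 4 not called, also 6 and 2 adjusted over the list alone and 5 and 2 without Ctl replicate 2 (camera adjusted p = 0.0363, 0.538 with an estimated correlation). Pparg, a nuclear receptor of tissue Tregs, rose from 5.92 and 11.2 to 85.6 and 184 normalized reads and the chemokine receptor gene Ccr8 rose by 1.21 on the log2 scale, while Il4ra fell by 1.14. Type 17 genes had 5 of 9 higher, 0 lower and 4 not called, also 5 adjusted over the list alone and 3 without Ctl replicate 2 (camera adjusted p = 0.00399, 0.633 with an estimated correlation). Rora rose by 1.67 on the log2 scale, and Il23r, a cytokine receptor, stood at 34.3 and 22.5 in Ctl and 285 and 91.6 in TSLPR WT Mi2. Without TSLPR WT Mi2 replicate 1 the camera adjusted p was 0.134 for type 2 and 0.0684 for type 17 genes, and without Ctl replicate 2 it was 0.0546 for type 2 genes. Sex-linked reads, with Xist at 25266 and 8678 in Ctl and 19.4 and 6.97 in TSLPR WT Mi2, moved with these groups.

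Immediate early and dissociation genes had 7 of 18 lower, 2 higher and 9 not called, also 7 and 2 adjusted over the list alone and 4 and 1 without Ctl replicate 2 (camera adjusted p = 0.0319, 0.633 with an estimated correlation). The camera adjusted p was 0.167 without Ctl replicate 2 and 0.0797 without TSLPR WT Mi2 replicate 1. The higher count was 1 without Ctl replicate 1 and 0 without TSLPR WT Mi2 replicate 2. Btg1, an antiproliferative gene, and Jun had log2 changes of -1.76 and -2.03. The other Treg lists did not pass camera, apart from the settings given below, and had members in both directions or few called. Treg core genes had 6 higher and 8 lower of 21 (camera adjusted p = 0.380), with Tigit, an inhibitory receptor, higher by 2.28 and Gpr83 lower with a log2 change of -2.69. Homing receptor genes had 9 and 5 of 26 (0.337), with Ccr10, a skin-homing receptor, higher by 2.71 and the gut receptor Ccr9 at a log2 change of -2.66. Suppressor effector genes had 7 and 4 of 17 (0.153), follicular regulatory genes 3 and 3 of 10 (0.749), type 1 genes 4 and 3 of 13 (0.944) and cell survival genes 5 and 7 of 20 (0.944). The p53 target genes had 3 and 3 of 23 (0.749), NF-kB response genes 0 and 4 of 18 (0.613), cholesterol synthesis genes 2 and 0 of 20 (0.334) and unfolded protein response genes 3 and 1 of 21 (0.337). Adjusted over the list alone, the higher and lower members were 6 and 8, 10 and 6, 7 and 4, 4 and 3, 4 and 3, 6 and 7, 4 and 3, 0 and 4, 0 and 0, and 2 and 0, in that order. Treg core genes had 3 and 7 without Ctl replicate 1 and 3 and 7 without TSLPR WT Mi2 replicate 1. NF-kB response genes had 0 and 2 and unfolded protein response genes 2 and 0 without Ctl replicate 1, and the latter 3 and 0 without TSLPR WT Mi2 replicate 1. Type 1 genes had 3 and 1 and cholesterol genes 1 and 0 without Ctl replicate 2. Suppressor effector genes had 6 and 2 without TSLPR WT Mi2 replicate 1. With TSLPR WT Mi2 replicate 2 left out, cell survival genes had 5 and 4 and cholesterol genes 0 and 1. Over 2 scalings and 4 left-out libraries the camera adjusted p of cholesterol genes ran from 0.0345, upward without TSLPR WT Mi2 replicate 1, to 0.727.

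B lymphocyte markers fell in 8 of 8 cases, also 8 adjusted over the list alone and 8 without Ctl replicate 2, and in 4 without Ctl replicate 1 (camera adjusted p = 1.0e-05, 0.538 with an estimated correlation). Ms4a1, which encodes CD20, stood at 1172 and 317 normalized reads in Ctl and 75.9 and 103 in TSLPR WT Mi2 Tregs, and Cd79b at 1237 and 727 against 505 and 578. Markers of CD8 T and NK cells had 4 of 7 lower, 0 higher and 3 not called, 5 adjusted over the list alone and 1 without Ctl replicate 2 (camera adjusted p = 0.0116, 0.0513 without TSLPR WT Mi2 replicate 1, 0.538 with an estimated correlation). Cd8a stood at 553 and 539 against 102 and 254. Conventional T cell markers, of which 4 are also on the resting list, had 6 of 7 lower and 1 not called, also 6 adjusted over the list alone and 4 without Ctl replicate 2 (camera adjusted p = 0.00228, 0.538 with an estimated correlation). Tcf7 stood at 9233 and 10650 against 1722 and 4375. Markers of dendritic cells, macrophages and monocytes had 2 higher and 4 lower of 13 (camera adjusted p = 0.101), plasma cell genes 2 and 2 of 5 (0.749), keratinocyte genes 0 and 0 of 4 (0.944), stroma and endothelium 1 and 1 of 3 (0.749) and erythroid genes 0 and 0 of 7 (0.212). With Ctl replicate 1 left out, erythroid genes had 0 and 4, dendritic cell markers 1 and 3, plasma cell genes 0 and 1 and stroma 0 and 1. With TSLPR WT Mi2 replicate 1 left out, erythroid genes had 0 and 4, dendritic cell markers 1 and 3 and stroma 1 and 0. With TSLPR WT Mi2 replicate 2 left out, dendritic cell markers had 1 and 6 and stroma 0 and 1, and plasma cell genes had 1 and 2 without Ctl replicate 2 or either TSLPR WT Mi2 library. Over the same 6 settings the camera adjusted p ran from 0.00209 to 0.548 for dendritic cell and from 0.00469 to 0.942 for erythroid markers. It was under 0.05 downward without Ctl or TSLPR WT Mi2 replicate 2 for the first, and without Ctl or TSLPR WT Mi2 replicate 1 for the second. Cd74 stood at 8763 and 5943 in Ctl and 3562 and 4220 in TSLPR WT Mi2 Tregs. Of the mast cell, basophil and eosinophil list, 2 members could be tested, too few for a list test.

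**Figure D4:**
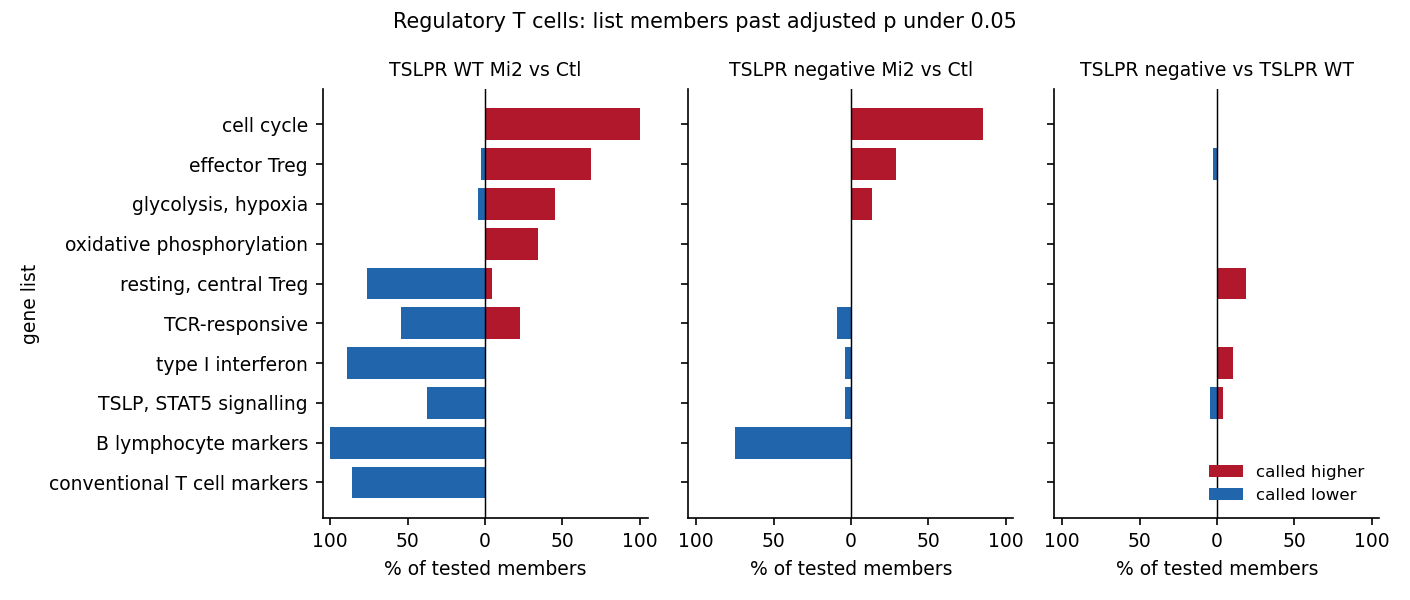
Percent of the tested members of 10 gene lists called higher (red) and lower (blue) in TSLPR WT Mi2 against Ctl, TSLPR-negative Mi2 against Ctl and TSLPR-negative against TSLPR WT Mi2 Tregs. Of the 34 cell cycle genes, 34, 29 and 0 were called higher in the 3 comparisons, and all 3 panels share the same axis.

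The next comparison asks whether TSLPR-negative Tregs of Mi2 mice differ from Ctl Tregs. Crlf2 fell from 395 and 742 normalized reads in Ctl to 51.5 in the TSLPR-negative library (log2 change -3.37, SE 0.367, adjusted p = 8.1e-04). Of 34 cell cycle and 38 effector Treg genes, 29 and 11 were called higher (camera adjusted p = 0.636 for both with an estimated correlation). Cdk1 stood at 462 and 275 in Ctl and 1581 in TSLPR-negative Tregs (log2 change 2.15, SE 0.310, adjusted p = 0.00397) and Klrg1 at 767 and 574 against 3023 (log2 change 2.19, SE 0.266, adjusted p = 0.0016). Without trend the calls of Crlf2, Cdk1 and Klrg1 ended (adjusted p = 0.0573, 0.0877 and 0.0723). In all, 384 of 12206 genes were called, 321 higher and 63 lower, and without Ctl replicate 2 the counts were 260 and 112, with 271 of these 372 genes shared. More were higher and fewer lower without Ctl replicate 1. Both counts rose without either TSLPR WT Mi2 library, of neither group compared here. Xist stood at 11903 and the Y-linked sum at 4.21 in the TSLPR-negative library, beside 25266 and 8678, and 8.28 and 2289, in Ctl.

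The largest fitted rises in TSLPR-negative against Ctl Tregs were in Slc17a8, Ltf, Lphn2, Ltb4r1, Scn4b, Dsg2, Mt1, Pls1, Pparg and Mt2, with log2 changes from 3.40 for Mt2 to 5.28 for Slc17a8. The largest fitted falls besides Crlf2 were in Igj, Bcl11a, Nr3c2, Rasgrp3, Cr2, Srpk3, Cacna1e, Mef2c and Pax5. Cr2, Pax5 and Igj mark B or plasma cells. Like Ms4a1 of B cells, Bcl11a, Rasgrp3, Srpk3, Cacna1e and Mef2c were highest in Ctl replicate 1 and lower in every Mi2 library. They may reflect B cells in the Ctl sorts, which was not tested. Nr3c2 was highest in Ctl replicate 2. Igj had 2 reads in the TSLPR-negative library, a ratio of 0.0130 (95% interval 0.00172 to 0.0522), and Nr3c2 had 3, a ratio of 0.0686 (0.0127 to 0.191). The calls of Srpk3, Cacna1e, Mef2c and Pax5 ended without Ctl replicate 1, and those of Nr3c2 and Cacna1e without Ctl replicate 2. With DESeq2 those of Nr3c2, Cacna1e and Mef2c ended (adjusted p = 0.0705, 0.109 and 0.170), and with voom those of Cacna1e, Mef2c and Pax5 (0.0751, 0.0847 and 0.0539).

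Cell cycle genes had 29 of 34 higher, 0 lower and 5 not called, 33 adjusted over the list alone and 28 without Ctl replicate 2 (camera adjusted p = 3.2e-41, 0.636 with an estimated correlation). Effector Treg genes had 11 of 38 higher, 0 lower and 27 not called, 14 higher and 1 lower adjusted over the list alone and 7 higher without Ctl replicate 2 (camera adjusted p = 5.9e-09, 0.636 with an estimated correlation). Lgals3 and S100a6 rose by 2.13 and 1.55 on the log2 scale. Glycolysis and hypoxia genes had 3 of 22 higher, 0 lower and 19 not called, 7 adjusted over the list alone and 3 without Ctl replicate 2 (camera adjusted p = 7.7e-04, 0.636 with an estimated correlation). Tpi1, a glycolytic enzyme gene, rose by 1.58 on the log2 scale. B lymphocyte markers had 6 of 8 lower, 0 higher and 2 not called, 7 adjusted over the list alone, 7 without Ctl replicate 2 and 3 without Ctl replicate 1 (camera adjusted p = 6.5e-13, 0.636 with an estimated correlation). Ms4a1 stood at 84.4 in the TSLPR-negative library against 1172 and 317 in Ctl. Resting and central Treg genes had 0 of 21 called by limma, edgeR or DESeq2, 0 adjusted over the list alone, 0 without Ctl replicate 2 and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00596 downward, 0.656 with an estimated correlation). Without Ctl replicate 1, TSLPR WT Mi2 replicate 1 or TSLPR WT Mi2 replicate 2, 1 member was lower. Bcl2 stood at 10038 and 6422 in Ctl and 6367 in TSLPR-negative Tregs (log2 change -0.33, SE 0.354). Type I interferon response genes had 1 of 28 lower, 0 higher and 27 not called, 2 adjusted over the list alone and 2 without Ctl replicate 2 (camera adjusted p = 6.7e-08, 0.0534 without Ctl replicate 1, 0.636 with an estimated correlation). The lower one was Oas1a, with a log2 change of -1.64, and its call ended without Ctl replicate 1 (adjusted p = 0.153) and without Ctl replicate 2 (0.0660). Without either TSLPR WT Mi2 library, 3 members were lower.

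Oxidative phosphorylation genes had 0 of 29 called by limma, edgeR or DESeq2, 0 adjusted over the list alone, 0 without Ctl replicate 2 and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00489 upward, 0.0534 without Ctl replicate 1, 0.703 with an estimated correlation). Genes that respond to T cell receptor signals had 2 of 22 lower, 0 higher and 20 not called, 3 adjusted over the list alone, 0 without Ctl replicate 2 and 1 without Ctl replicate 1 (camera adjusted p = 0.00659, 0.0537 without Ctl replicate 2, 0.636 with an estimated correlation). These were Egr2 and Egr3, with log2 changes of -1.20 and -1.41. Egr2 was also the lower one of 18 immediate early and dissociation genes, with 0 higher and 17 not called, 1 adjusted over the list alone and 0 without Ctl replicate 2 (camera adjusted p = 0.0317, 0.636 with an estimated correlation). That p was 0.339 without Ctl replicate 2, 0.0549 without TSLPR WT Mi2 replicate 1 and 0.0533 without TSLPR WT Mi2 replicate 2. In this list 2 genes were lower without Ctl replicate 1. Crlf2 was the lower one of 24 TSLP and STAT5 signalling genes, with 0 higher and 23 not called, 1 adjusted over the list alone and 1 without Ctl replicate 2 (camera adjusted p = 0.0171, 0.0824 without Ctl replicate 2, 0.636 with an estimated correlation).

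Class I antigen presentation and cholesterol synthesis genes had 0 of 19 and 0 of 20 called by limma, edgeR or DESeq2, 0 adjusted over each list alone, 0 without Ctl replicate 2, and 1 and 2 lower at an unadjusted p under 0.05. The camera adjusted p was 0.0173 and 0.0317 downward, with adjusted p = 0.703 with an estimated correlation for both. It was 0.400 without Ctl replicate 2 for the first and 0.174 without Ctl replicate 1 for the second. Without either TSLPR WT Mi2 library, 1 cholesterol gene was lower. Dendritic cell, macrophage and monocyte markers had 4 of 13 lower, 0 higher and 9 not called, also 4 adjusted over the list alone and 4 without Ctl replicate 2 (camera adjusted p = 0.0476, 0.662 with an estimated correlation). This list had 2 lower and 1 higher without Ctl replicate 1 (camera adjusted p = 0.174), and the camera adjusted p was 0.0869 with DESeq2 size factors and 0.0774 with upper quartile scaling. The lower ones were Cd74, H2-Eb1, H2-Aa and H2-Ab1, class II pathway genes that B cells also express, with log2 changes of -1.46, -1.81, -1.80 and -2.08, and B lymphocyte markers fell with them. Cst3 of this list stood at 1349 against 786 and 1016 in Ctl and was not called. Suppressor effector genes had 4 of 17 higher and 0 lower, 7 and 3 adjusted over the list alone and 2 higher without Ctl replicate 2 (camera adjusted p = 0.112), with Lgals1 higher by 1.31. Without either TSLPR WT Mi2 library 1 was lower. The other 16 lists with a test did not pass camera, and the lowest adjusted p with an estimated correlation over all lists was 0.636.

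Among them, homing receptor genes had 1 of 26 higher (camera adjusted p = 0.561), type 2 genes 1 of 12 (0.165), type 1 genes 1 of 13 (0.226), Treg core genes 1 of 21 (0.800), unfolded protein response genes 1 of 21 (0.303) and cell survival genes 2 of 20 (0.423), with 0 lower in each. Adjusted over the list alone they had 1, 3, 1, 1, 2 and 2 higher in that order, and Treg core genes had 2 lower. Plasma cell genes had 1 of 5 lower (0.110) and 2 lower adjusted over the list alone. The p53 target, NF-kB response, type 17 and follicular regulatory genes had 0 of 23, 18, 9 and 10 called (0.963, 0.135, 0.356 and 0.674). At an unadjusted p under 0.05 these 4 lists had 2, 0, 0 and 1 higher and 0, 2, 0 and 1 lower. Erythroid, CD8 T and NK cell, keratinocyte, stroma and conventional T cell markers had 0 of 7, 7, 4, 3 and 7 called (0.179, 0.108, 0.963, 0.362 and 0.105). Their unadjusted counts were 0, 0, 0, 1 and 0 higher and 0, 1, 0, 0 and 1 lower. The median, mean and test of Treg core, follicular regulatory and plasma cell genes differed in sign. With Ctl replicate 1 left out, homing receptor genes had 3 higher and type 1, type 2 and unfolded protein response genes 2 each. With Ctl replicate 2 left out, type 1 and unfolded protein response genes had 0 higher and cell survival genes 1. With either TSLPR WT Mi2 library left out, homing receptor genes had 3 higher and 1 lower, type 2 and unfolded protein response genes 2 higher each and p53 target genes 1. Lower then were 2 Treg core, 1 follicular regulatory and 2 plasma cell genes. Over 2 scalings and 4 left-out libraries the camera adjusted p of plasma cell genes ran from 0.0101 to 0.285, under 0.05 downward without either TSLPR WT Mi2 library, and that of erythroid markers from 0.00246, upward without Ctl replicate 2, to 0.543.

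The last Treg comparison asks what differs between TSLPR-negative and TSLPR WT Tregs when both come from Mi2 mice. Crlf2 fell from 816 and 715 normalized reads in TSLPR WT to 51.5 in the TSLPR-negative library (log2 change -3.86, SE 0.367, adjusted p = 1.4e-04). Of 21 resting Treg genes 4 were called higher in TSLPR-negative Tregs (camera adjusted p = 0.719 with an estimated correlation). Among them, Ly6c1 stood at 1411 against 108 and 256 (log2 change 3.08, SE 0.402, adjusted p = 0.0037) and Bcl2 at 6367 against 995 and 1923 (log2 change 2.20, SE 0.354, adjusted p = 0.0129). Gpr83, an orphan receptor of Tregs, stood at 4934 against 479 and 828 (log2 change 2.97, SE 0.305, adjusted p = 2.9e-04), while Lgals3 fell by 1.63 on the log2 scale (SE 0.340, adjusted p = 0.0391), not called with quantile normalization (0.0612). Without trend the calls of Crlf2, Ly6c1, Bcl2, Gpr83 and Lgals3 all ended (adjusted p = 0.104, 0.193, 0.216, 0.132 and 0.264). In all, 115 of 12206 genes were called, 90 higher and 25 lower in TSLPR-negative Tregs, and 7 of them lie on the X or Y chromosome. Both counts rose when any replicate was left out, where 1 pair alone sets the spread, and were 149 and 93 with DESeq2. Foxp3, Gata3, Il7r and Il1rl1 had log2 changes of -0.07, -0.11, 0.53 and 0.12 and were not called.

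After Xist and Tsix, the largest fitted rises in TSLPR-negative against TSLPR WT Mi2 Tregs were in Cyp4f18, Ifit1, Ly6c1, Enah, Ltf, Cdhr3, Gpr83 and Trib3, with log2 changes from 2.96 for Trib3 to 3.86 for Cyp4f18. The Y-linked Eif2s3y was at least 607-fold lower, with 0 reads in the TSLPR-negative library, and Ddx3y had 1 read, a ratio of 4.1e-04 (95% interval 1.0e-05 to 0.00228). Hey1, a Notch target, had 2 reads, a ratio of 0.0483 (0.0057 to 0.179). Boc, Apold1, Rassf6, Ank3, Rab39b and Slc24a3 had log2 changes from -3.38 for Boc to -2.71 for Slc24a3. The calls of Boc, Rassf6, Rab39b and Slc24a3 ended without TSLPR WT Mi2 replicate 1 (adjusted p = 0.0572, 0.0573, 0.0730 and 0.0918). Those of Cdhr3 and Slc24a3 ended with DESeq2 size factors (0.0623 and 0.0553), those of Hey1 and Ifit1 with DESeq2 (0.0630 and 0.134), and those of Eif2s3y, Ddx3y, Hey1, Boc, Apold1, Rab39b and Slc24a3 with voom (0.0579 to 0.165).

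Resting and central Treg genes had 4 of 21 higher, 0 lower and 17 not called, 13 adjusted over the list alone and 5 without Ctl replicate 2 (camera adjusted p = 5.9e-10, 0.719 with an estimated correlation). Evl and Actn1 rose by 1.78 and 1.61 on the log2 scale. Their calls ended without TSLPR WT Mi2 replicate 1, and more members were called without Ctl replicate 1 or TSLPR WT Mi2 replicate 2. Type I interferon response genes had 3 of 28 higher, 0 lower and 25 not called, 21 adjusted over the list alone and 10 without Ctl replicate 2 (camera adjusted p = 2.0e-17, 0.719 with an estimated correlation). More were also called higher without Ctl replicate 1 or either TSLPR WT Mi2 library. Usp18 stood at 554 against 71.4 and 131, and Irf7 rose by 1.51 on the log2 scale. The calls of Irf7, Evl and Actn1 ended with DESeq2 size factors (adjusted p = 0.0604, 0.0599 and 0.0623) and with quantile normalization (0.0698 each). Effector Treg genes had 1 of 38 lower, 0 higher and 37 not called, 13 adjusted over the list alone, 4 without either Ctl library and 10 without TSLPR WT Mi2 replicate 2 (camera adjusted p = 1.7e-10, 0.719 with an estimated correlation). Cell cycle genes had 0 of 34 called by limma, edgeR or DESeq2 and 0 adjusted over the list alone, with 22 lower at an unadjusted p under 0.05, 2 lower without either Ctl library, 1 lower without TSLPR WT Mi2 replicate 2 and a median log2 change of -0.69 (camera adjusted p = 3.8e-17, 0.719 with an estimated correlation). Type 17 genes had 1 of 9 lower, 0 higher and 8 not called, 3 adjusted over the list alone and 2 without Ctl replicate 2 (camera adjusted p = 0.00121, 0.0824 without TSLPR WT Mi2 replicate 1, 0.719 with an estimated correlation). It had 2 lower without Ctl replicate 1, and without TSLPR WT Mi2 replicate 2, 4. The lower one was Ahr, a ligand-activated transcription factor, at 381 against 1416 and 1496. Xist at 11903 against 19.4 and 6.97, and the Y-linked sum at 4.21 against 5707 and 4382, move with each of these groups.

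Conventional T cell markers had 0 of 7 called by limma, edgeR or DESeq2, 3 higher adjusted over the list alone and 0 without Ctl replicate 2 (camera adjusted p = 0.00125 upward, 0.719 with an estimated correlation), with Tcf7 at 7106 against 1722 and 4375. Without Ctl replicate 1, 2 of them were higher, without TSLPR WT Mi2 replicate 1, 1 and without TSLPR WT Mi2 replicate 2, 3. CD8 T and NK cell markers had 0 of 7 called by limma, edgeR or DESeq2, 2 higher adjusted over the list alone and 0 without Ctl replicate 2 (camera adjusted p = 0.0408 upward, 0.719 with an estimated correlation). That p was 0.0763 without Ctl replicate 1 and 0.170 without TSLPR WT Mi2 replicate 1, and 2 members were higher without TSLPR WT Mi2 replicate 2. Erythroid genes, whose globin paralogs share reads, had 0 of 7 called by the same 3 tools, 0 adjusted over the list alone, 0 without Ctl replicate 2 and 4 higher without TSLPR WT Mi2 replicate 1 (camera adjusted p = 9.8e-04 upward, 0.719 with an estimated correlation). At an unadjusted p under 0.05, 3 genes of each of these 3 lists were higher.

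TSLP and STAT5 signalling genes had 1 of 24 higher, which was Bcl2, 1 lower, which was Crlf2, and 22 not called, with 2 and 1 adjusted over the list alone and 2 and 1 without Ctl replicate 2 (camera adjusted p = 0.0102 upward, 0.120 without TSLPR WT Mi2 replicate 1, 0.719 with an estimated correlation). Without Ctl replicate 1 or TSLPR WT Mi2 replicate 1, 2 were higher, and without TSLPR WT Mi2 replicate 2, 4. Class I antigen presentation, cholesterol synthesis and oxidative phosphorylation genes had 0 of 19, 0 of 20 and 0 of 29 called by limma, edgeR or DESeq2, 0 adjusted over each list alone and 0 without Ctl replicate 2. At an unadjusted p under 0.05, 2 of the first were higher, 5 of the second lower and 0 of the third either way. The camera adjusted p was 0.0213 upward, 7.1e-05 downward and 0.0337 downward, with adjusted p = 0.765, 0.719 and 0.781 with an estimated correlation. It was 0.786 for the first without TSLPR WT Mi2 replicate 1, and 0.252 and 0.633 for the others without TSLPR WT Mi2 replicate 2. Without TSLPR WT Mi2 replicate 1, 4 cholesterol genes were lower, and without TSLPR WT Mi2 replicate 2, 1 class I gene was higher. The other 18 lists with a test did not pass camera, and the lowest adjusted p with an estimated correlation over all lists was 0.719.

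Among them, cell survival genes had 2 of 20 higher and 1 lower (camera adjusted p = 0.669), follicular regulatory genes 1 and 2 of 10 (0.619), homing receptor genes 2 and 0 of 26 (0.480), Treg core genes 1 and 0 of 21 (0.220), unfolded protein response genes 1 and 0 of 21 (0.619) and p53 target genes 0 and 1 of 23 (0.619). Adjusted over the list alone the counts were 5 and 3, 2 and 3, 4 and 2, 2 and 1, 1 and 0, and 3 and 1, in that order. Genes that respond to T cell receptor signals and suppressor effector, type 2, type 1, immediate early, NF-kB response and glycolysis genes had 0 of 22, 17, 12, 13, 18, 18 and 22 called by limma (0.173, 0.388, 0.164, 0.302, 0.164, 0.742 and 0.173). Their unadjusted counts at p under 0.05 were 7, 2, 2, 2, 5, 0 and 1 higher and 3, 3, 3, 0, 1, 1 and 2 lower. B lymphocyte, dendritic cell, plasma cell, keratinocyte and stroma markers had 0 of 8, 13, 5, 4 and 3 called (0.480, 0.962, 0.218, 0.962 and 0.684). Their unadjusted counts were 0, 0, 0, 0 and 1 higher and 0, 1, 1, 0 and 0 lower. With either Ctl library left out, the counts were 3 and 3 for cell survival, 2 and 2 for follicular regulatory, 2 and 0 for Treg core and 2 and 1 for p53 target genes, and 1 and 0 for suppressor effector, type 1 and immediate early genes each. With TSLPR WT Mi2 replicate 1 left out they were 2 and 0 for cell survival, 0 and 2 for follicular regulatory, 1 and 0 for homing receptor, 1 and 0 for p53 target and 1 and 0 for immediate early genes. With TSLPR WT Mi2 replicate 2 left out they were 2 and 3 for follicular regulatory, 4 and 2 for homing receptor, 3 and 1 for Treg core, 1 and 1 for p53 target, 2 and 2 for suppressor effector, 1 and 1 for type 1 and 0 and 3 for type 2 genes. Genes that respond to T cell receptor signals then had 2 and 0, and immediate early genes 1 and 0. Over 2 scalings and 4 left-out libraries the camera adjusted p of type 2 genes ran from 0.0197, downward without TSLPR WT Mi2 replicate 2, to 0.555. For unfolded protein response, follicular regulatory, suppressor effector, cell survival, dendritic cell, keratinocyte and stroma genes the median, mean and test differed in sign.

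For genes called between TSLPR WT Mi2 and Ctl Tregs, the TSLPR-negative library lay between the means of the 2 groups for 3065 of 3383, or 90.6% (95% exact Clopper-Pearson interval 89.6 to 91.6, over genes, which are not independent). Its median position, with Ctl at 0 and TSLPR WT Mi2 at 1 on the log2 scale, was 0.54, and it was 0.62 for rising and 0.40 for falling genes. In 100 simulations with the TSLPR-negative library at the TSLPR WT Mi2 level, between 55.5% and 58.8% of genes lay between the means. With Ctl replicate 2 defining the genes and Ctl replicate 1 as reference the share was 82.0%, and with the roles exchanged it was 86.2%.

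Changes of TSLPR WT Mi2 and of TSLPR-negative Mi2 Tregs against Ctl correlated across genes at 0.765, where simulated unchanged groups with the same controls gave 0.409. Their covariance was 0.494 against a simulated 0.0546, a difference of 0.439. Among the called genes 315 were higher in both, 56 were lower in both and 1 went opposite ways. Chance would also give overlap here, since the Ctl libraries are shared. With 1 Ctl library for each comparison, a division chosen after seeing the data, the correlation was 0.616 with Ctl replicate 1 for TSLPR WT Mi2 and replicate 2 for TSLPR-negative Tregs, and 0.569 with these exchanged. Then 370 and 246 genes were higher in both, 31 and 59 lower in both and 10 and 2 went opposite ways.

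**Figure D5:**
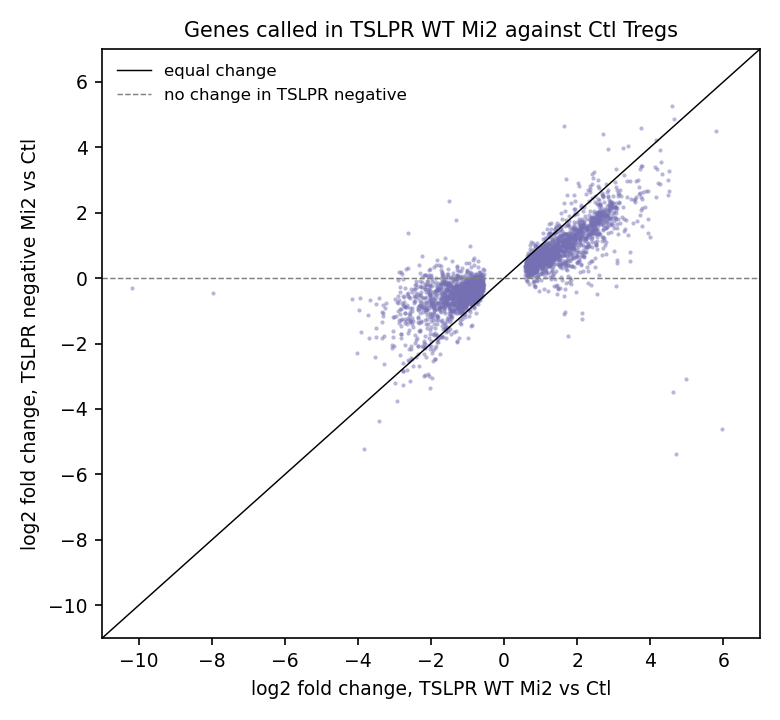
Log2 fold change of TSLPR-negative Mi2 against Ctl Tregs (vertical) by that of TSLPR WT Mi2 against Ctl (horizontal) for the 3383 genes called in the latter, 1 point per gene, with a solid line for equal change and a dashed line for no change. The TSLPR-negative value of 90.6% of these genes lies between the Ctl and TSLPR WT Mi2 means, and Xist and Y-linked genes stand apart.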

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

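The tests of the cell cycle genes, of the 2 Mi2 epidermis libraries and of the position of the TSLPR-negative library were chosen only after their results were seen, and the mixture test was rewritten after its values were seen. A difference between groups drew attention here: 115 of 12206 genes differed by limma between TSLPR-negative and TSLPR WT Tregs of Mi2 mice, 90 higher and 25 lower. The count rose when any replicate was left out, where 1 pair alone sets the spread.

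Xist and Y-linked reads split the Treg libraries, with Xist at 25266 and 8678 in Ctl, 19.4 and 6.97 in TSLPR WT Mi2 and 11903 in TSLPR-negative Mi2 Tregs, and Ctl replicate 2 holding both kinds of reads. Sex as the whole cause of the cell cycle rise would put the TSLPR-negative library at the level of Ctl replicate 1, but its 34 cell cycle genes stood higher by a median of 1.29 on the log2 scale (1.21 to 1.42 over genes, higher in 34 of 34), where the 2 Ctl libraries differed by 0.74. If sex were the whole cause of the difference by TSLPR status, the 2 Ctl libraries would part in step with the Y-linked share. That share was 45.4% in Ctl replicate 2. Yet the slope over 108 autosomal genes was 0.0145 (-0.110 to 0.152 over genes), which argues against a sex effect that Ctl mice share. The slope rests on 1 library of each kind. An effect of sex that appears only in Mi2 mice could still contribute and was not tested, since TSLPR status and sex-linked reads change together there. TSLPR status itself remains open too, with 1 TSLPR-negative library to stand for it.

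Mi2 epidermis replicate 2 lay nearer to WT than replicate 1: 3160 of 4085 called genes, 77.4%, changed less in replicate 2, with median absolute log2 changes of 1.70 and 1.33 in replicates 1 and 2. Undeleted keratinocytes as the whole cause would need a share of 45.5% (39.2 to 54.2) from Chd4, but 60 genes at under 5% of WT in replicate 1 stood at a median of 8.63% in replicate 2 (5.95 to 10.5), and 0 of 60 reached that share. A single scaling factor would leave the spread of log2 changes alone. The spread in replicate 2 was 0.825 of that in replicate 1 (0.814 to 0.837 over genes). A smaller share of undeleted cells, the mitochondrial share of replicate 1 and a difference in the degree of the Mi2 effect between animals may each contribute and stay open. The last of these is a biological difference and was not tested.

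The TSLPR-negative library lay between the Ctl and TSLPR WT Mi2 means for 90.6% of 3383 called genes. In 100 simulations at the TSLPR WT Mi2 level the share was 55.5 to 58.8%, and it was 82.0% and 86.2% with the Ctl libraries divided between calling and reference, so the choice of genes is unlikely to account for all of it, within what those simulations assume. A mixture of Ctl-like and Mi2-like cells and a partial response cannot be told apart, because the cell cycle median minus the effector median was 11.3 percentage points, with -8.38 to 28.3 over pairs of libraries. On the linear scale the cell cycle genes had gone 50.8% of the way (48.4 to 52.2), interferon genes 54.4% (49.4 to 63.4), resting genes 41.1% (36.3 to 48.1), effector genes 39.5% (30.8 to 44.2) and B lymphocyte markers, of other cells, between 98.9% and 108%. TSLPR status and an effect of sex stay open as untested explanations of this pattern.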

How the results depend on the processing

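The alternatives on transcript choice, edgeR without a filter, mitochondrial genes left out and list counts without libraries in doubt were chosen after seeing the data. With no filter on low values limma called 0 genes in each Treg comparison, with 5043, 1741 and 1942 at an unadjusted p under 0.05 for TSLPR WT Mi2 against Ctl, TSLPR-negative against TSLPR WT Mi2 and TSLPR-negative Mi2 against Ctl, where edgeR without a filter called 3846, 525 and 811. The cause was not tested, and the same holds for the other changes below. At an adjusted p under 0.01 the counts were 1364 in epidermis and 1933, 16 and 136 in Tregs, and with all transcripts they were 5260, 230 and 598. For TSLPR-negative against TSLPR WT Mi2, 115 became 57 with quantile normalization, 72 with DESeq2 size factors and 242 with DESeq2, and limma without trend called 3 there and 1 for TSLPR-negative Mi2 against Ctl (1280 and 1545 at an unadjusted p under 0.05). edgeR called 4283, 3480, 149 and 450 genes in the 4 comparisons. Leaving out 1 library at a time, where a lone sample is assumed to vary like the other groups, gave 1113 to 5815 in epidermis, 2504 to 2742 for TSLPR WT Mi2 against Ctl, 159 to 453 for TSLPR-negative against TSLPR WT Mi2 and 372 to 687 for TSLPR-negative Mi2 against Ctl. In epidermis, leaving the 50 most abundant genes out of scaling gave 3853 genes and moved the median of all genes from -0.03 to -0.16, and leaving out mitochondrial genes gave 4280, 1531 higher and 2749 lower, with a median of -0.27. Pairing libraries by replicate number gave 5170 genes in epidermis and 4361 for TSLPR WT Mi2 against Ctl (3361 with the same libraries unpaired), although deviations of equal numbers correlated at only 0.123 and 0.0917. Of all lists tested, camera passed 11, 15, 12 and 13, or 0 each with an estimated correlation, and fry passed 13, 0, 0 and 0. Camera passed 8 to 14, 12 to 16, 8 to 12 and 9 to 13 lists with 1 library left out. The share of genes for which TSLPR-negative Tregs lay between was 91.7% for genes called by DESeq2, 91.8% at a mean of at least 50, 87.7 to 90.3% with 1 library left out and 86.2% and 82.0% with the Ctl libraries divided. No called gene from the naming rule reversed, with transcript choice not checked. Of the 119, 118, 33 and 50 called genes that the naming rule gave in epidermis, TSLPR WT Mi2 against Ctl, TSLPR-negative against TSLPR WT Mi2 and TSLPR-negative Mi2 against Ctl, 19, 24, 30 and 49 were not called without trend and 9, 118, 33 and 50 with no filter. Quantile normalization ended 3, 2, 11 and 7 of these calls.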

Other observations

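No test in this part was chosen after its result was seen. H19, an imprinted gene, had the largest fitted log2 rise among called genes in Mi2 epidermis, 10.63, and the hypothesis tested was that imprinted genes rise there as a group. Of 39 listed imprinted genes without H19, 19 could be tested, of which 5 rose, 3 fell and 11 were not called, with a median log2 change of 0.17 and a mean of 0.55. The camera p was 0.322 upward, and 0.395 with an estimated correlation, which neither shows a rise of the group nor that it is unchanged. Igf2 and Slc38a4 rose by 5.10 and 4.57 on the log2 scale, Igf2r by 1.88, and Ascl2 fell by 3.83.

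All 4 epidermis libraries held Y-linked reads, with Ddx3y at 209 and 275 normalized reads in WT and 223 and 244 in Mi2, Eif2s3y at 218 and 268 against 121 and 242, Kdm5d at 147 and 186 against 66.3 and 132 and Uty at 81.4 and 156 against 23.9 and 102. The last 3 were lowest in Mi2 replicate 1. Xist stood at 9.92 and 1.45 in WT and 18.6 and 1.36 in Mi2. Chd4 in Tregs stood at 11757 and 15129 in Ctl, 12374 and 13659 in TSLPR WT Mi2 and 15392 in TSLPR-negative Mi2, and was not called against Ctl (log2 changes -0.04 and 0.21).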
